A study of Rattus norvegicus with 4 samples.

How the data were processed

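The series measured binding of the glucocorticoid receptor in the hippocampus of adrenalectomized male rats 1 hour after 300 or 3000 µg/kg corticosterone, with 1 GR and 1 IgG library per dose. Per the labels' protocols, chromatin of several animals of a group was pooled after shearing, and the same chromatin was divided between antibodies, so that a library stands for a pool and not for an animal. The labels' protocols describe the preparation for sequencing only for the libraries at 3000 µg/kg, with 18 rounds of amplification; that of the libraries at 300 µg/kg is not given in the sources used here. Each deposited file lists aligned reads, 1 per line, with a count of 1 in every line, so that the unit is the read count with no normalized value used here. The submitters' processing notes name the build rn4 and the tools bedtools and MACS; the aligner, the versions and the filters are not given in the sources used here. Every library held 468802 reads, all of 36 bases, and no position and strand held more than 1 read. The identical totals mean that the reads were reduced to a common number before deposit, by a step not given in the sources used here.

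Reads were counted as follows, by choices fixed before the data were examined. Reads on chromosomes 1 to 20 and X were used, between 458480 and 461308 per library, and the 5' end of each read was moved 75 bases in its own direction. Windows of 300 bases were placed every 100 bases. The expected count of a window was the largest of the genome mean of the GR library (0.0509 reads per window at 3000 µg/kg) and the IgG counts of the same dose in the surrounding 1, 5 and 10 kb, scaled to the window and to library size. A window was called at a Poisson p of at most 1e-05 with at least 4 reads, and overlapping windows were merged into regions. MACS itself was not used here. The number of regions found with the GR and IgG libraries exchanged, divided by the number found for GR, served as an estimate of the false discovery rate. The span of the chromosomes, 2718671228 bases, was taken from the highest read position on each.

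Regions of one dose were read in the libraries of the other dose, with ratios scaled to library size and exact Clopper-Pearson 95% intervals. Overlap of region sets required 1 shared base and was set against 1000 shuffles within chromosomes. The dose difference was an exact two-sided binomial test of the GR reads of both doses in each region called at either, at the ratio of library sizes, with Benjamini-Hochberg adjustment over all such regions and a threshold of 0.05. This test sums the outcomes no more probable than the one seen. Where a dose held all reads of a region, both tails were counted for the dose with the larger library and a single tail for the other. Log2 ratios used a pseudocount of 0.5 reads. A count of 0 was taken to allow up to 3 reads.

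Regions were named by a fixed rule. It took the 15 regions of lowest p at 3000 µg/kg and the 10 at 300 µg/kg whose IgG count was at most 25% of the GR count, and the 5 regions of lowest dose-difference p in each direction. The rule also named genes near regions, but no rn4 genome or annotation was used here, and the only gene table at hand was of another build. The share of regions with a glucocorticoid response element, the comparison of regions with and without one, the position of regions relative to genes and the gene lists were therefore not run, and regions are given by their coordinates, counted from 1. Reads on the mitochondrial genome and on unplaced sequences entered none of the comparisons above and are described apart. Unplaced sequences were also added to the calling of regions as an alternative setting.

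After seeing the data, a further way of counting was added. A plus-strand and a minus-strand read whose 5' ends lay 50 to 140 bases apart were merged into 1 fragment, each read being used once, on the reading that such pairs are mostly both ends of an amplified fragment, which the labels do not describe. Merging also joins reads of different fragments that lie close together. This falls most on the GR library at 3000 µg/kg, where the bins from 40 and 140 bases, on either side of the maximum, held 5589 and 5425 pairs, against 330 to 1096 pairs in the other libraries. Between 70236 pairs (GR at 3000 µg/kg) and 121324 pairs (IgG at 3000 µg/kg) were merged. Random division of the fragments (20 draws), plus-strand reads alone, the addition of unplaced sequences and shuffles to IgG read positions were also added after seeing the data. The alternatives fixed beforehand were a p threshold of 1e-07, windows of 600 bases, pooled IgG libraries, the IgG library of the other dose, no IgG, no shift, at least 8 reads, all reads as deposited, other definitions of overlap, regions reduced to 200 bases on each side of their centre, and scaling by reads outside the regions.

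The caller was tested on simulated libraries with an even background, the measured share of paired ends and 200 sites of known strength. All simulated fragments had the same length, so that each pair of their ends lay within the merging range. In the real libraries the distances varied, and false regions on merged fragments may be more frequent than in the simulation. At 3000 µg/kg, counting every read recovered 62.0% of sites with a mean of 4 fragments, 98.0% at 8 and 100.0% at 16 and 32, with 360 regions at no site; the exchange of libraries gave 899 regions there, and so overstated the known false regions. Counting merged fragments recovered 46.0%, 82.0% and 100.0%, with 0 regions at no site and 1 in the exchange. At 300 µg/kg every read recovered 56.0%, 92.0%, 98.0% and 100.0% of sites at 4, 8, 16 and 32 fragments with 495 other regions and 551 in the exchange, and merged fragments recovered 32.0%, 90.0%, 98.0% and 100.0% with 2 other regions and 2 in the exchange. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.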

Results

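Binding of the glucocorticoid receptor (GR) to chromatin was measured in the hippocampus of male Sprague-Dawley rats by chromatin immunoprecipitation followed by sequencing (ChIP-seq). GR is a nuclear receptor that binds DNA when occupied by a glucocorticoid such as corticosterone, the main circulating glucocorticoid of the rat. The animals had been adrenalectomized, which removes their own corticosterone, and were killed 1 hour after an injection of 300 or 3000 µg/kg corticosterone. At each dose 1 library was made with a GR antibody and 1 with normal rabbit IgG as the background control, so that the series held 4 libraries and 1 per group. Each library held 468802 aligned reads of 36 bases. Of these, 461308 reads of the GR library and 459217 of the IgG library at 3000 µg/kg lay on chromosomes 1 to 20 and X, against 459136 and 458480 reads at 300 µg/kg. No group had a replicate, and every p-value below therefore compares the reads of a pair of libraries and not the doses or antibodies as conditions. Unless a range over draws is named, intervals are exact 95% binomial intervals, which cover counting error only. Intervals and p-values on reads take each read as independent. Where both ends of a fragment were counted, the intervals are too narrow and the p-values too small.

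Many reads had a partner on the other strand at a short, fixed distance. In each library the starts of plus-strand and minus-strand reads showed 1 sharp maximum of distances, at 90 to 99 bases in both GR libraries, at 100 to 109 bases in the IgG library at 300 µg/kg and at 80 to 89 bases in the IgG library at 3000 µg/kg. Reads were paired with a read from the other strand 50 to 140 bases away, each read being used once. Opposite ends of 1 amplified fragment would leave such pairs. They took in 30.5% of reads in the GR library and 52.8% in the IgG library at 3000 µg/kg, and 37.0% and 41.0% at 300 µg/kg. The labels do not describe this pairing. In the GR library at 3000 µg/kg the maximum stood on a broad shoulder, with 5589 pairs in the bin from 40 bases and 5425 in that from 140, against 880 and 330 in its IgG library, so that pairs in this range also included reads of different fragments. Counts of reads are accompanied below by counts in which such a pair of ends was merged and counted once as a fragment, a choice made after seeing the data. After merging, the GR libraries held 391072 fragments at 3000 µg/kg and 374255 at 300 µg/kg, and the IgG libraries held 337893 and 364468.

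**Figure D1:**
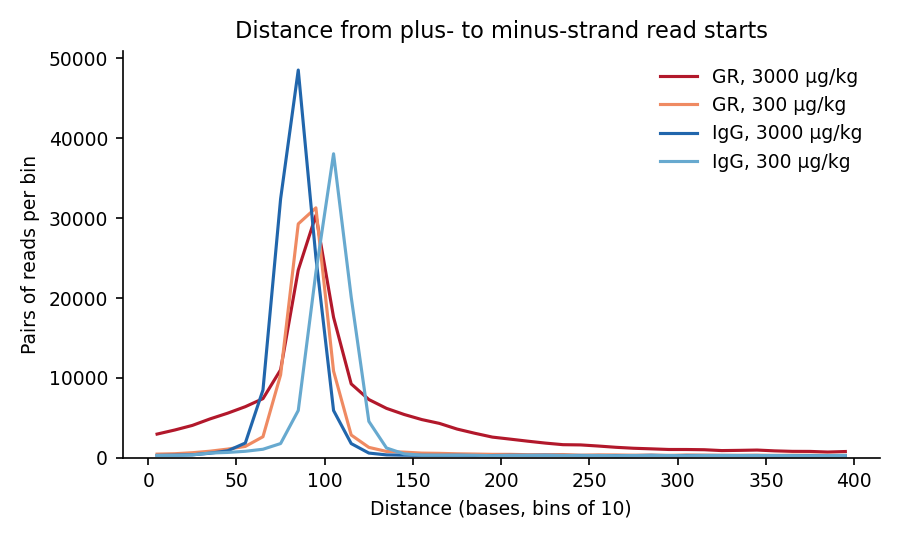
Number of pairs of a plus-strand and a minus-strand read (y axis) by the distance between their starts in bases (x axis, bins of 10 bases), 1 line per library. The highest bins held 30358 pairs in the GR library and 48530 pairs in the IgG library at 3000 µg/kg, and 31286 and 38052 pairs at 300 µg/kg.

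The first comparison asked where in the genome GR was bound after 3000 µg/kg corticosterone. GR reads exceeded the IgG background in 6255 regions with a median width of 400 bases, which covered 2797700 bases or 0.103% of the chromosomes. The strongest region lay on chromosome 8 from 52001001 to 52001800 (all positions are in the rat build rn4) and held 85 GR reads against 2 IgG reads (exact Poisson p = 7.18e-127). It was followed by chromosome 1 from 118371301 to 118372000, with 77 GR reads and 2 IgG reads, and by chromosome 2 from 180112801 to 180113500, with 56 GR reads and 1 IgG read. The region at chromosome 10 from 60195701 to 60196500 held 82 GR reads and 5 IgG reads. Of the 15 regions of lowest p, 7 held 0 IgG reads of this dose, which allows up to 3 reads. Among them were regions on chromosome 3 from 5190901 to 5191600 with 44 GR reads, on chromosome 4 from 150233001 to 150233600 with 36, on chromosome 7 from 74250801 to 74251500 with 36, on chromosome 14 from 84115501 to 84116300 with 44 and on chromosome 2 from 140547701 to 140548900 with 52.

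Across these 15 regions the GR library held 36 to 85 reads and the IgG library of the same dose 0 to 5. Most regions were far weaker: the median region held 6 GR reads, 1176 regions held 10 or more and 229 held 20 or more. Exchanging the roles of the GR and IgG libraries gave 1300 regions, 20.8% of the number called for GR, or 13.8% with the IgG library of the other dose as background. With the ends of fragments merged 3044 regions were called for GR and 111 in the exchange, 3.65% of the GR number. Of the 6255 regions counted on reads, 2988 (47.8%) overlapped a region counted on fragments.

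After 300 µg/kg fewer and weaker regions were found. GR reads exceeded IgG in 1510 regions, and the highest count in any of them was 28 GR reads. The strongest region lay on chromosome 1 from 226342801 to 226343400, with 24 GR reads and 0 IgG reads at this dose (exact Poisson p = 1.26e-55). Next came chromosome 1 from 77410101 to 77410700 with 22 GR reads, chromosome 3 from 119237001 to 119237600 with 18 and chromosome 5 from 74011501 to 74012100 with 17, each with 0 IgG reads. The regions at chromosome 10 from 55856101 to 55856700 and at chromosome 20 from 27270801 to 27271400 held 28 and 23 GR reads against 2 IgG reads each.

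The remaining regions of lowest p at 300 µg/kg lay on chromosome 18 from 5426201 to 5426800 with 16 GR reads, chromosome 10 from 52900401 to 52901000 with 16, chromosome 7 from 127156001 to 127156600 with 14 and chromosome 11 from 77875501 to 77876100 with 24, and all 4 held 0 IgG reads of this dose. The 10 regions of lowest p held 29 to 61 reads in the GR library at 3000 µg/kg, more than at 300 µg/kg in 10 of 10. The exchange of libraries weighed more on this set than on that at 3000 µg/kg. Exchanging the GR and IgG libraries gave 954 regions, 63.2% of the number called, or 98.2% with the IgG library of the other dose as background. Merging the ends of fragments left 324 regions against 41 in the exchange, or 12.7%. Of the 1510 regions counted on reads, 317 (21.0%) overlapped a region counted on fragments.

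**Figure D2:**
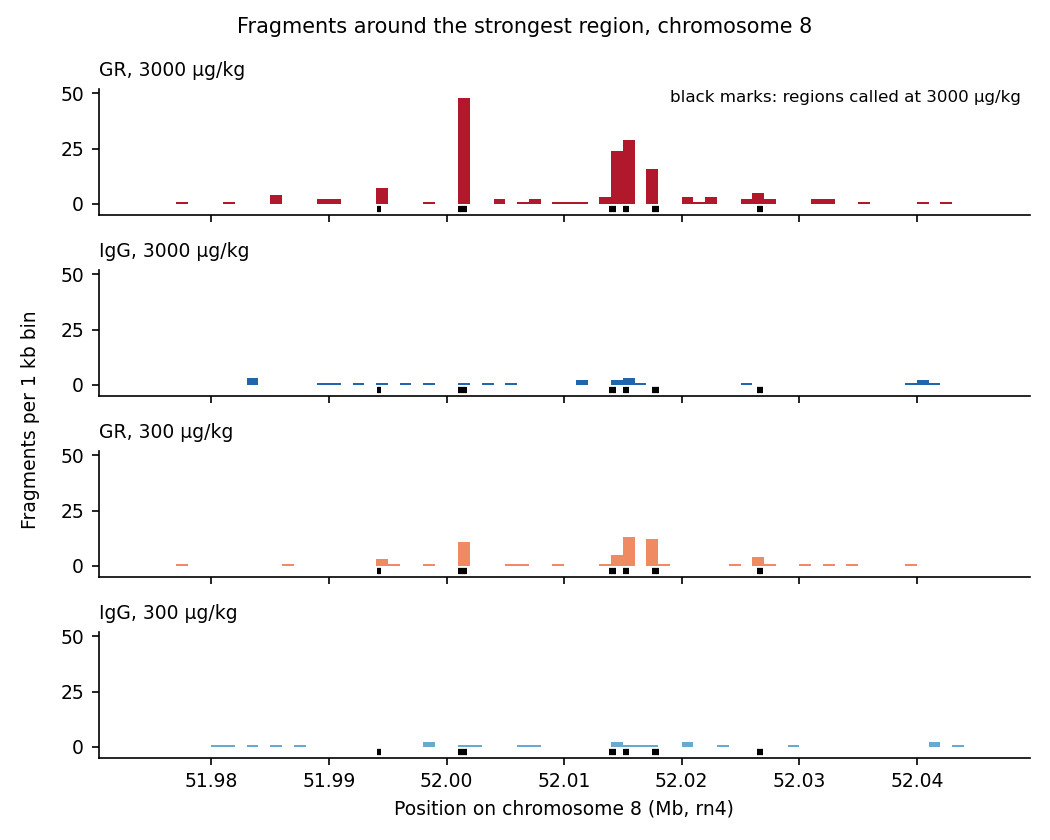
Fragments per bin of 1 kb (y axis) along chromosome 8 in Mb (x axis, rn4) around the strongest region, 1 panel per library with a common y axis; black marks are the regions called at 3000 µg/kg with the ends of fragments merged. The region from 52001001 held 47 GR and 1 IgG fragments at 3000 µg/kg and 11 and 1 at 300 µg/kg.

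Regions chosen at one dose were next read in the libraries of the other dose, which had no part in choosing them. In the 6255 regions chosen at 3000 µg/kg the GR library at 300 µg/kg held 8579 reads and its IgG library 1330 reads, a ratio of 6.44 at equal library size (95% interval 6.08 to 6.83). More GR than IgG reads were found in 3048 of these regions (48.7%), equal numbers in 2749 and fewer in 458 (7.32%). All 15 regions of lowest p at 3000 µg/kg held more GR than IgG reads at 300 µg/kg, including chromosome 8 from 52001001 with 19 against 2 and chromosome 1 from 118371301 with 21 against 2. In the 1510 regions chosen at 300 µg/kg the libraries at 3000 µg/kg held 7999 GR reads and 521 IgG reads, a ratio of 15.3 (14.0 to 16.7), with more GR than IgG reads in 817 regions (54.1%) and fewer in 60.

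The GR to IgG ratio at 300 µg/kg rose with the strength of a region at 3000 µg/kg. The 3010 regions with 4 to 5 GR reads at 3000 µg/kg had a GR to IgG ratio of 4.01 (3.64 to 4.43) at 300 µg/kg. The ratio was 5.95 (5.37 to 6.60) in the 2069 regions with 6 to 9 reads and 8.36 (7.39 to 9.49) in the 947 regions with 10 to 19. In the 229 regions with 20 to 85 reads it was 15.01 (12.3 to 18.5), and 92.1% of them (87.9 to 95.3%) held more GR than IgG reads at 300 µg/kg, against 35.0% (33.3 to 36.7%) of the weakest class. On reads the intervals of the 4 ratios did not overlap. With the ends of fragments merged the ratios were 5.65 (4.85 to 6.60), 7.30 (6.32 to 8.46), 9.88 (8.08 to 12.2) and 13.6 (9.35 to 20.6) from the weakest to the strongest class, and the intervals of neighbouring classes overlapped. On fragments, 98.3% (90.9 to 99.96%) of the 59 strongest regions and 44.2% (41.6 to 46.7%) of the 1501 weakest held more GR than IgG fragments at 300 µg/kg. False regions may weigh most on the weak classes. On reads at 3000 µg/kg the exchange of libraries gave 1300 regions against 6255 for GR. With at least 8 reads required it gave 15 against 1681. False regions would lower the ratio of a class, and their part in the rise was not tested.

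**Figure D3:**
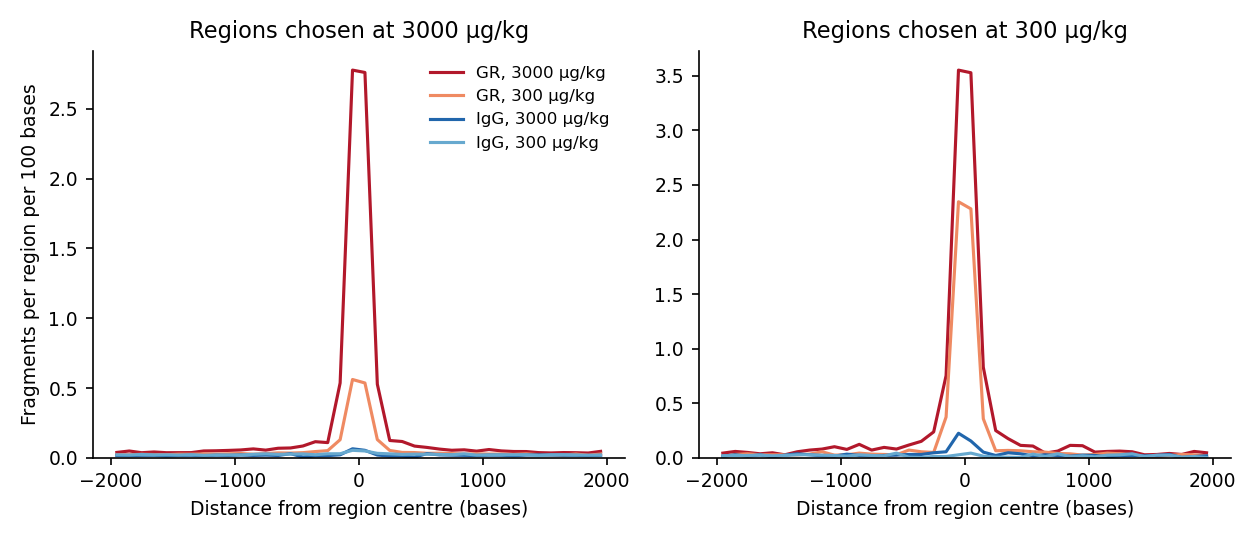
Mean number of fragments per region and 100 bases (y axis) by the distance in bases from the region centre (x axis), for the 3044 regions chosen at 3000 µg/kg (left) and the 324 chosen at 300 µg/kg (right), 1 line per library; the y axes differ between panels. At the centre of the 3000 µg/kg regions the GR library of that dose reached 2.78 and the GR library at 300 µg/kg 0.561. The IgG libraries reached 0.0647 and 0.0539 there. At the centre of the 300 µg/kg regions the GR libraries reached 3.55 at 3000 µg/kg and 2.35 at 300 µg/kg. The IgG library at 3000 µg/kg peaked there too, at 0.225 against 0.0154 at -1950 bases. That at 300 µg/kg, used in the choice of these regions, reached 0.0432.

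The region sets of the doses overlapped far more than placed at random. Of the 1510 regions at 300 µg/kg, 485 (32.1%) shared at least 1 base with a region at 3000 µg/kg, whereas 1000 shuffles within chromosomes gave 3.14 on average and 9 at most. Of the 15 regions of lowest p at 3000 µg/kg, 4 were also among the 10 of lowest p at 300 µg/kg. These 4 lay on chromosome 1 at 77410101 and 226342801 and on chromosome 10 at 52900401 and 55856101. With the ends of fragments merged 211 of 324 regions (65.1%) were shared, against at most 3 in the shuffles. The 1025 regions called only at 300 µg/kg held 816 GR against 221 IgG reads at 3000 µg/kg in sum, a ratio of 3.68 (3.16 to 4.28), compared with 23.8 (21.2 to 26.8) in the shared regions. Since shared regions were those called on the reads at 3000 µg/kg, a higher ratio in them was set by the division itself. The median of these 1025 regions was 0 GR reads at 3000 µg/kg, so that the summed reads came from a minority of them, whereas the median shared region held 11.

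GR occupancy was compared between the doses in the 7280 regions called at either. At an adjusted p of at most 0.05 (exact binomial test, two-sided, Benjamini-Hochberg adjusted), 699 regions held more GR reads at 3000 µg/kg, 2 held more at 300 µg/kg and 6579 were not called. The difference of lowest p lay on chromosome 10 from 60195701 to 60196500, where 82 reads at 3000 µg/kg stood against 1 at 300 µg/kg, a ratio of 81.6 (14.2 to 3262; adjusted p = 1.29e-19, exact binomial). Chromosome 20 from 6752101 to 6752900 held 57 reads against 2, a ratio of 28.4 (7.50 to 239.9), and chromosome 15 from 3932501 to 3933100 held 54 against 3, a ratio of 17.9 (5.81 to 89.6). Chromosome 10 from 67867101 to 67867700 held 44 against 2 (adjusted p = 4.5e-08, exact binomial). Chromosome 2 from 140547701 to 140548900 held 52 against 4 (adjusted p = 2.02e-08, exact binomial). The test took no account of IgG, of which these 5 regions held 0 to 5 reads at 3000 µg/kg and 0 at 300 µg/kg.

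Other strong regions showed a smaller ratio of doses. At chromosome 10 from 55856101 to 55856800 the GR libraries held 45 reads at 3000 µg/kg and 28 at 300 µg/kg, a ratio of 1.60 whose interval of 0.976 to 2.66 included 1. The ratio was 1.53 (0.894 to 2.68) at chromosome 11 from 77875501, 2.32 (1.42 to 3.92) at chromosome 1 from 226342801 to 226343500 and 4.45 (2.68 to 7.76) at chromosome 8 from 52001001. It ranged from 1.60 to 81.6 over the 15 regions of lowest p at 3000 µg/kg. Over the 10 of lowest p at 300 µg/kg it ranged from 1.53 to 2.76. The former were chosen on reads at 3000 µg/kg and the latter on reads at 300 µg/kg. Selection thus raised the ratio in the former and lowered it in the latter. The regions with more reads at 300 µg/kg lay on chromosome 16 from 17846101 to 17846500 and on chromosome 17 from 75584901 to 75585500, and each held 8 reads at 300 µg/kg and 0 at 3000 µg/kg (adjusted p = 0.0428, exact binomial). Their unadjusted p of 0.00383 (exact binomial) came from a single tail. At the library ratio of 1.005 the opposite outcome was slightly more probable, and the test left it out. Regions with 7 reads against 0 had p = 0.00768 (exact binomial) and were not called (adjusted p = 0.0621). With both tails counted, 8 reads against 0 would stand close to that p, so that these calls rest on the handling of tails.

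**Figure D4:**
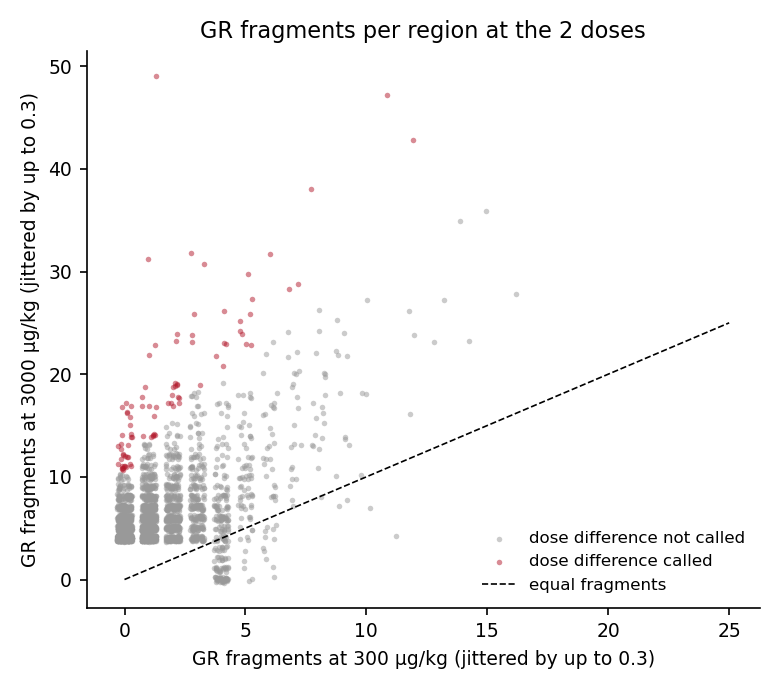
GR fragments per region at 300 µg/kg (x axis) and at 3000 µg/kg (y axis) for the 3156 regions called at either dose with the ends of fragments merged, 1 point per region. The 87 red points were called different between the doses and all lie above the dashed line of equal fragments; the point near 1 fragment on the x axis and 49 on the y axis is the region on chromosome 10 from 60195701.

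The number of calls depended on the counting. With the ends of fragments merged 87 of 3156 regions held more fragments at 3000 µg/kg and 0 at 300 µg/kg, against 738 and 3 at an unadjusted exact binomial p under 0.05. Scaling by the reads outside the regions in place of all reads gave 1256 and 2 regions on reads, and moved the median log2 ratio of doses from 2.32 to 2.43. Selection raised this median, since most of the regions were chosen on GR reads at 3000 µg/kg. The library ratio moved from 1.005 to 0.927. Regions with all reads at 3000 µg/kg were then tested on a single tail and no longer on both tails. The rise from 699 to 1256 thus did not measure scaling alone. At a p threshold of 1e-07 for the regions, 1171 of 3592 regions held more reads at 3000 µg/kg and 19 at 300 µg/kg. Except under the scaling by reads outside the regions, regions with all reads at 300 µg/kg were tested on a single tail.

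Counting reads in the regions chosen on the same reads raises the counts of the dose that chose them. Regions were therefore also chosen on a random part of the fragments of a dose and read in the rest, over 20 draws, a choice made after seeing the data. Regions chosen in this way at 3000 µg/kg, 977 in the median draw, held 15.4 times as many GR as IgG fragments in the part not used for choosing (14.2 to 16.8, the lowest and highest draw, as for the other ranges of this paragraph). Their ratio of GR fragments at 3000 to 300 µg/kg was 3.34 (3.24 to 3.66). In regions chosen at 300 µg/kg, 74.5 in the median draw, the ratio of doses was 2.96 (2.50 to 3.25), so that more GR fragments lay in the regions at the higher dose whichever library chose them. The ratio of doses after subtraction of IgG was 3.51 (3.35 to 3.87) and 3.02 (2.51 to 3.23). With 1 library per dose these ratios cannot be separated from differences between immunoprecipitations.

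GR reads were concentrated in a small part of the genome at both doses. The 6255 regions of 3000 µg/kg took 10.2% of the reads of the GR library of that dose (10.1 to 10.3%), a share raised by the selection of the regions, and 0.251% of the reads of its IgG library. The same regions took 1.87% (1.83 to 1.91%) of GR reads and 0.290% of IgG reads at 300 µg/kg. The 1510 regions of 300 µg/kg took 1.70% (1.67 to 1.74%) of GR reads at 300 µg/kg and 1.73% (1.70 to 1.77%) at 3000 µg/kg. Of the IgG reads they took 0.0199% and 0.114%. The GR share at 300 µg/kg was likewise raised by selection. The region sets of 3000 and 300 µg/kg covered 0.103% and 0.0221% of the chromosomes. IgG reads of the dose that did not choose the regions, at 0.290% and 0.114%, were thus also denser there than an even spread. With regions chosen on a random part of the fragments and read in the rest, the shares of the choosing dose were 1.76% at 3000 µg/kg and 0.0890% at 300 µg/kg, in the fewer regions found at that lower depth. Merging the ends of fragments lowered the share of the GR library at 3000 µg/kg to 5.25% and that at 300 µg/kg, in the regions of 300 µg/kg, to 0.466%.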

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

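The counts of merged fragments and the tests of the spread of the ratio of doses in this part were chosen only after the result was seen. The GR libraries of the doses differed by the exact binomial test in 699 regions with more reads at 3000 µg/kg and in 2 regions with more at 300 µg/kg, which made these results stand out as a difference between groups. The test compared 1 library per dose in regions chosen on the same reads, 6255 of them at 3000 µg/kg and 1025 only at 300 µg/kg, so that selection contributed to the imbalance. The 2 calls at 300 µg/kg rest on a single tail of the test, as described above. In regions called at a p threshold of 1e-07 the numbers were 1171 and 19. On merged fragments 87 and 0 regions were called; how much of this fall came from counting both ends of a fragment, and how much from merging reads of different fragments, was not tested.

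On merged fragments the ratio of doses varied between regions, taken as a set, by more than counting error gave. Over the 129 regions with at least 20 GR fragments of both doses together, the chi-square per degree of freedom around 1 common ratio was 1.38 (p = 0.0022 from 10000 exact binomial draws), which argues against counting error alone. The region on chromosome 10 from 60195701 to 60196500 carried part of this: without it the value was 1.28 (p = 0.0173 from such exact draws), and it was 1.45 with a minimum of 15 fragments (p = 0.0001, the smallest that the draws can give) and 1.24 with a minimum of 25 (p = 0.0899). That region, with 49 fragments at 3000 µg/kg and 1 at 300 µg/kg, was the only 1 of the 129 called apart from the common ratio (adjusted p = 0.00843, exact binomial). No more than 6 of the 129 had an unadjusted exact binomial p under 0.05. Whether the merging of reads of different fragments shifted the ratio between regions was not tested. Unspecific signal shared with IgG cannot be told apart from a regional dose response, since regions without an IgG fragment gave 1.40 over 35 regions (p = 0.0617 from such exact draws), 1.27 over 104 regions at a minimum of 15 (p = 0.0325) and 1.09 over 15 regions at a minimum of 25 (p = 0.37), and the minimum decided the side of 0.05; a dose response that differs between regions and a difference between single immunoprecipitations may both contribute.

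Signal was also found on sequence outside the comparisons. On sequences not placed on a chromosome, 63 regions were called for GR at 3000 µg/kg against 18 with GR and IgG exchanged, and 18 regions at 300 µg/kg against 11 in the exchange. The strongest lay on the unplaced part of chromosome 6 from 214001 to 214700, with 25 GR reads and 1 IgG read at 3000 µg/kg and 1 GR read at 300 µg/kg. The next lay on the sequence without a chromosome from 57516301 to 57517200, with 33 and 6 GR reads at 3000 and 300 µg/kg and 0 IgG reads at either dose.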

How the results depend on the processing

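Merged fragment ends, plus-strand reads alone, added unplaced sequences, random division and shuffles to IgG positions were chosen only after the result was seen. The number of regions at 3000 µg/kg, 6255, lay between 6040 and 8310 with windows of 600 bases, pooled IgG, the IgG library of the other dose, no IgG, no shift or added unplaced sequences. It was 3422 at a p threshold of 1e-07, 1681 with at least 8 reads, 3044 with merged ends and 1977 on plus-strand reads. At 300 µg/kg the number, 1510, lay between 1328 and 2229 under the former settings and was 424, 129, 324 and 179 under the latter, in the same order. Stricter thresholds and fewer counted reads lower these numbers by construction. In the same order, regions with GR and IgG exchanged fell from 1300 to 129, 15, 111 and 50 at 3000 µg/kg and from 954 to 69, 14, 41 and 24 at 300 µg/kg, a larger fall than that of the GR regions. With pooled IgG the exchange set both IgG libraries against 1 GR library and gave 3433 and 3432 regions, no estimate of false calls at equal depth. The GR to IgG ratio in libraries of the other dose stayed above 1 under each setting run, at 6.44 to 10.4 for regions chosen at 3000 µg/kg and 15.3 to 19.9 for those chosen at 300 µg/kg. Shared regions numbered 482 to 499 under other definitions of overlap; shuffles to IgG positions gave 6.34 shared regions on average and 15 at most, in place of 3.14 and 9. Shared regions were 254 at 1e-07 and 211 with merged ends, out of fewer regions by construction. The share of GR reads in regions was 5.25% with merged ends and 1.76% with regions chosen on a random part of the fragments at 3000 µg/kg, and 0.466% and 0.0890% at 300 µg/kg. Regions with more GR reads at 3000 µg/kg numbered 1256 when scaled by reads outside the regions, 1171 at 1e-07 and 87 with merged ends. Those with more at 300 µg/kg numbered 2, 19 and 0 in that order. Scaling by reads outside the regions also changed which dose was tested on a single tail where it held all reads. This was the dose of 3000 µg/kg under that scaling and 300 µg/kg otherwise, so that the 1256 did not measure scaling alone. At an unadjusted exact binomial p under 0.05 the numbers fell at 1e-07, from 1994 to 1763 and from 104 to 68. The rise at 1e-07 therefore lay in the adjustment, made over 3592 regions in place of 7280. Counting all reads as deposited changed none of these results, since no position and strand held more than 1 read. The alternatives for response elements, position relative to genes and gene lists were not run. At 0.0509 reads per window, a window needed at least 4 reads to be called, so that weak binding was not detectable at this depth, and leaving out a replicate was not possible with 1 library per group.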

Other observations

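The tests of even scatter and of split regions in this part, and the thinning at 300 µg/kg, were chosen only after the result was seen, as was the merging of fragment ends on which all numbers but the mitochondrial ones rest. GR regions at 3000 µg/kg were not evenly spread over the chromosomes. Chromosome 12 held 190.2 regions per 100 Mb (95% Poisson interval 152.8 to 234.1) and chromosome 10 186.1 (161.5 to 213.3), whereas chromosome 2 held 90.6 (79.4 to 103.0) and chromosome X 14.9 (9.57 to 22.2). Regions also lay in groups: 640 of the 3044 regions lay within 20 kb of a neighbour, in 282 groups, of which 17 held 4 or more regions and 5 held 5 or more. The group around the strongest region, on chromosome 8 from 51994101 to 52026900, held 6 regions in 32.8 kb with 125 GR and 7 IgG fragments at 3000 µg/kg and 46 and 5 at 300 µg/kg. A group of 6 on chromosome 17 from 19197801 to 19231500 held 61 GR and 3 IgG fragments at 3000 µg/kg and 9 and 1 at 300 µg/kg. On chromosome 20 from 6752201 to 6763800, 5 regions held 76 and 19 GR fragments at 3000 and 300 µg/kg, and 4 regions on chromosome X from 128303201 to 128317300 held 20 and 11 with no IgG fragment at either dose.

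Outside the nuclear genome, the GR libraries held fewer mitochondrial reads than their IgG controls. At 3000 µg/kg 1244 GR reads stood against 2312 IgG reads, a ratio of 0.538 (0.502 to 0.577), and at 300 µg/kg 2596 against 2992, a ratio of 0.868 (0.823 to 0.915).

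The grouping of GR regions was set against 3 technical explanations. Neighbouring regions within 20 kb formed 358 pairs, whereas even scatter along each chromosome gave 72.2 pairs on average and 97 at most in 1000 shuffles. Uneven coverage was represented by positions drawn from IgG fragments, which gave at most 122 pairs in 1000 sets. Of the 358 pairs, 10.3% lay within 1 kb, so that most pairs were not pieces less than 1 kb apart. This share cannot decide on broad regions split by the caller. Overlapping called windows had already been merged, and pieces of a region of several kb could lie more than 1 kb apart. Several separate binding sites near one another may lie behind the groups, as may broad regions that were split. Either is a hypothesis found and tested on the same data. Differences in mappability or chromatin accessibility that IgG reads do not carry were not tested.

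The low density of regions on chromosome X was partly a matter of depth. Males carry a single X, and its IgG density over both doses was 42.5% of the autosomal density. In the IgG library at 3000 µg/kg alone it was 43.2%, and autosomes at that dose were thinned to this share. They fell from 118.1 to 28.5 regions per 100 Mb (27.4 to 29.7 over 20 draws), above the upper limit of 22.2 for X. By that limit a single X alone did not account for the whole difference, but the gap shrank from 7.91-fold to 1.91-fold. The limit takes regions as independent, whereas 4 of the 24 regions on X lay in 1 group. It may therefore be too low, and the comparison with it does not settle the matter. Differences between chromosomes in general cannot be told apart from a property of X. Thinned chromosomes 2, 14, 18, 9 and 13 held 19.2, 20.4, 20.9, 21.0 and 21.6 regions per 100 Mb, below the limit of 22.2. The other thinned autosomes lay above it. A peculiarity of the libraries at 3000 µg/kg stays open too: X held 2 regions at 300 µg/kg, below the range of 3 to 14 for its share of IgG fragments (one-sided binomial p = 0.0104), yet that range ignores that calls fall faster than depth, and thinned autosomes at 300 µg/kg predict 3.02 regions.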
